A study of Mus musculus with 8 samples.

How the data were processed

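RNA was profiled in 8 samples of mouse CD8+ T cells with the OT-1 receptor and Cas9, 4 transduced with a vector without a guide and 4 with a vector for a guide RNA against Dhx37. Per the labels' protocols, cells were taken up in TRIzol, RNA was purified with a PureLink RNA mini kit, and polyadenylated RNA was made into libraries with a TruSeq strand-specific kit. The values are normalized TPM per Ensembl gene, 1 column per library, deposited by the authors in a table of the whole series. Per the submitters' processing notes, kallisto and sleuth were used with the mouse build mm10; their versions, the transcript annotation and the settings for strand are not given in the sources used here. TPM divide estimated reads by transcript length and scale each library to a fixed total before any further normalization, so a change in a few abundant genes moves all others, and mitochondrial genes took between 1.66% and 13.3% of a library. The table's TPM sum to between 809369 and 978255 per library. Because TPM do not hold depth, no counting intervals or detection limits are given. A value of 0 is reported as listed at 0. Of 20 genes that all cells use, 0 were at 0 in any library. kallisto assigns reads that fit several transcripts by estimation, so values of near-identical paralogs are uncertain.

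Columns were assigned to libraries by their titles and groups were taken from the sample titles. The titles of the vector libraries also carry the letters NTC, which no label explains. Of 30387 gene identifiers, 30186 matched a symbol in the annotation and 201 did not; 17 symbols were carried by several identifiers, whose TPM were summed, which left 30370. No pair of libraries held identical values. Coordinates, GC content and transcript length come from the GENCODE annotation of the same build. Genes with at least 1 TPM in at least 4 of the 8 libraries were tested, 11913 in all. Values were transformed to log2(TPM + 1), with a pseudocount of 1, and compared between groups with limma 3.58.1 in R 4.3.3 (linear model with group only, empirical Bayes with a trend on mean expression, two-sided). The p-values had Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. limma on log values was used because TPM are not counts. All adjusted p-values of genes come from this test. For Dhx37 and for the first principal component an exact two-sided permutation test over 70 arrangements was added; the smallest p it can give with 4 against 4 libraries is 0.0286.

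Gene lists were written before the data were examined, 37 in all, for ribosome assembly, p53 and stress responses, T cell effector, memory, signalling and migration functions, cell cycle, metabolism, and markers of other cell types. A list needed at least 3 tested members. Lists were compared with limma's camera with a preset correlation between genes of 0.01, adjusted over the 37 lists, and again with an estimated correlation and with fry. For each list the members past the test are given over all genes and adjusted over the list alone. The rule for named genes was also set beforehand: Dhx37; the 12 largest rises and the 12 largest falls among genes past the threshold whose groups do not overlap, leaving out predicted, clone and pseudogene names. For each list past camera or with at least 2 members past the threshold, it added up to 4 members past it or, where none was, the 2 with the smallest p. One gene that this rule adds is not reported here. Other names are said to be chosen after their values were seen; genes named in a comparison without vector 1 and 2 alone are among the 4 members with the smallest p of their list there.

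Alternatives listed before the data were examined changed the pseudocount to 0.1, 0.5 and 5, and the filter to none or to a mean of 5 TPM. Others used median-of-ratios scaling, quantile normalization or identifiers without summing. Further ones were each library left out in turn, the replicate number as a block, limma with array weights, without a trend and with robust estimation, an adjusted p of 0.1 and a minimum log2 fold change of 1. After the data were seen, comparisons without vector 1 and 2 and without vector 3 and 4 were added. A correction was also added in which, per library, a loess trend (span 0.3) of the deviation from the gene's mean on GC content and log length was removed, for the 11862 genes with such values. The correction was also run with the replicate block and without vector 1 and 2. Principal components were computed on centred log2(TPM + 1) of the tested genes. Figures were drawn in Python 3.11.15.

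The procedure was tested on simulated data with 11913 genes of which 100 carried a log2 change of 1 and 100 a change of 2 between sgDhx37 and vector. With the real spread between libraries it recovered 47% of the former and 89% of the latter. The 0 false calls there were fixed beforehand, since the group difference of every unchanged gene had been removed. With independent noise it recovered 59% and 91% with 14 false calls. The changed genes were drawn from those with a mean log2(TPM + 1) above 2, and the change was added on that scale. The recovery therefore does not cover genes of lower abundance, such as Gzmd, Gzme and S100a8. The guide's sequence and cut site and the reads themselves were not used here.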

Results

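Polyadenylated RNA was sequenced from mouse OT-1 Cas9 CD8+ T cells, cytotoxic T cells that carry one transgenic receptor for an ovalbumin peptide together with the Cas9 nuclease. The cells had been transduced with adeno-associated virus 6 that carried either no guide (vector, described as empty, 4 libraries) or a guide RNA against Dhx37 (sgDhx37, 4 libraries). DHX37 is a DEAH-box RNA helicase that acts in maturation of the small ribosomal subunit, and the comparison asks how the transcriptome of T cells given this guide differs from that of cells given the vector. The series describes the 4 libraries of each group as biological replicates, and the p-values below measure the spread between libraries. The vector libraries formed pairs. Spearman correlations were 0.988 between vector 1 and 2, 0.985 between vector 3 and 4, and 0.866 to 0.922 across these pairs. In comparisons without vector 1 and 2 or without vector 3 and 4, the vector group is 1 such pair. Their p-values measure the spread within that pair and within sgDhx37, and leave out the difference between the pairs. The deposited values are TPM per gene, which sum to between 809369 and 978255 in a library. TPM keep no record of the number of reads, so sequencing depth is unknown. Between 11493 and 12058 genes per library reached 1 TPM, and 11913 genes were tested. Fold changes are differences of mean log2(TPM + 1), sgDhx37 minus vector, a scale that understates the change of genes with low TPM; ratios of mean TPM are given where so named.

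Dhx37 itself (ENSMUSG00000029480, chromosome 5, 125413858 to 125434121 in mm10, minus strand) was transcribed in all 8 libraries. Its level was 13.3 ± 4.58 TPM in vector and 10.2 ± 0.504 TPM in sgDhx37 (mean ± SD, n = 4 each). The vector libraries 1 to 4 held 15.2, 18.8, 9.08 and 10.03 TPM, and the sgDhx37 libraries held 9.48, 10.2, 10.7 and 10.4 TPM. The log2 fold change was -0.30 ± 0.21 (SE), with an adjusted p of 0.422 in limma, and an exact two-sided permutation test of the 8 values gave p = 0.400. In a comparison without vector libraries 1 and 2, chosen after the data were seen, the difference turned to 0.08 ± 0.07, with an adjusted p of 0.492. With vector libraries 3 and 4 left out instead, likewise chosen afterwards, it was -0.68, with an adjusted p of 6.8e-04. A correction of all 8 libraries for GC content and transcript length, also chosen afterwards, left -0.089 ± 0.077 (adjusted p = 0.488), and without vector 2 alone it was -0.12 (adjusted p = 0.768). The table gives transcript abundance and does not show whether the transcripts carry insertions or deletions at the guide's target.

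Mitochondrially encoded transcripts and GC-rich genes set vector libraries 1 and 2 apart from the other 6 libraries. Mitochondrial genes took 2.02% and 1.66% of the TPM in vector 1 and 2, against 9.80% and 8.99% in vector 3 and 4 and between 8.60% and 13.3% in sgDhx37. In the difference between vector 1 and 2 and vector 3 and 4, the fifth of genes with the lowest GC content had a median of -1.02 (log2) and the fifth with the highest GC content a median of 0.67. Spearman's rho of that difference with GC content was 0.742 across 11862 genes, which are not independent replicates. The first principal component held 77.1% of the variance and gave scores of -55.6 and -76.0 to vector 1 and 2 and of 14.1 to 30.7 to the other 6 libraries. Its scores differed between the groups by less than the spread (exact two-sided permutation test over 70 arrangements, p = 0.343). The second component held 9.43% of the variance, with scores of -0.89 to 29.7 in vector and of -13.4 to -5.30 in sgDhx37. Spearman correlations between libraries were 0.976 to 0.995 among the other 6, 0.988 between vector 1 and 2, and 0.866 to 0.935 between these and the rest.

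**Figure D1:**
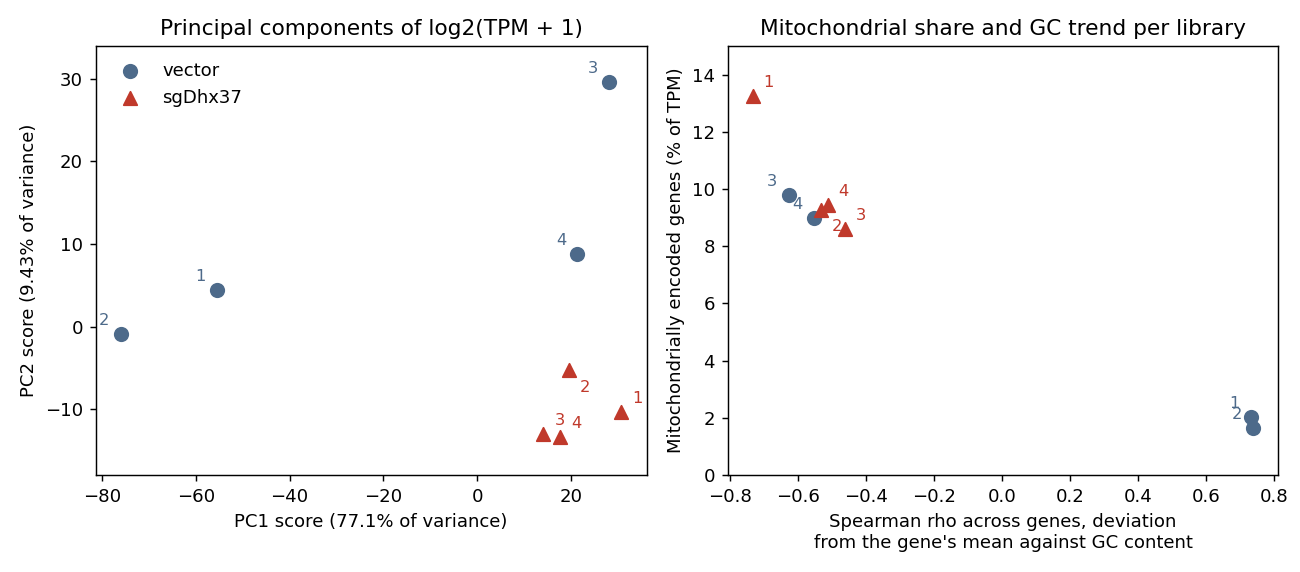
Left, scores of the 8 libraries on the principal components of log2(TPM + 1), with the share of variance on each axis; right, the percent of TPM from mitochondrially encoded genes against Spearman's rho, across genes, between a library's deviation from the gene's mean and GC content. Circles are vector and triangles sgDhx37 libraries, with replicate numbers; vector 1 and 2 lie apart in both plots, at 2.02% and 1.66% mitochondrial TPM.

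Transcripts assigned to genes for 3 granzymes, 2 cytokines and 1 checkpoint receptor rose in sgDhx37 cells. Gzmc, which encodes a serine protease of cytotoxic granules, rose from 8.33 ± 2.49 TPM in vector to 43.4 ± 1.91 TPM in sgDhx37 (mean ± SD, n = 4 each), a ratio of mean TPM of 5.21. Its neighbours Gzmd and Gzme rose from 0.263 ± 0.194 to 2.18 ± 0.361 TPM and from 0.154 ± 0.115 to 1.74 ± 0.193 TPM. Both were under 1 TPM in every vector library, so they passed the filter through the sgDhx37 libraries alone and could be tested only as rises. Ifng, the interferon gamma gene, rose from 4.44 ± 0.685 to 9.74 ± 1.40 TPM, and Csf2, which encodes the cytokine GM-CSF, from 5.85 ± 1.01 to 12.1 ± 0.719 TPM. Havcr2, which encodes the inhibitory receptor TIM-3, rose from 1.12 ± 0.209 to 3.74 ± 0.214 TPM. The log2 fold changes were 2.29 ± 0.19 (SE, adjusted p = 0.00585) for Gzmc, 1.34 ± 0.14 (0.0160) for Gzmd and 1.25 ± 0.11 (0.00853) for Gzme. They were 0.98 ± 0.14 (0.0327) for Ifng, 0.94 ± 0.13 (0.0280) for Csf2 and 1.17 ± 0.11 (0.00871) for Havcr2. In mm10 Gzmc lies on chromosome 14 at 56231441 to 56234656, with Gzmd at 56129556 to 56132608 and Gzme at 56117626 to 56120625. These granzymes and the serpin Serpinb9b belong to families of near-identical paralogs, so the split of reads among family members is uncertain. After the GC and length correction the adjusted p of Ifng was 0.0683, at 0.73 ± 0.18, and the other 5 genes stayed below 0.05. Ifng and Csf2 lost their calls without vector 1, 3 or 4, and Gzmd without vector 3. Of the 6 genes Gzmc and Gzme alone kept theirs without sgDhx37 2 and none did without sgDhx37 1, 3 or 4.

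Other genes with large rises belonged to no single list. Trim2, which encodes an E3 ubiquitin ligase, was the most abundant of them and rose from 310.2 ± 28.2 to 905.9 ± 110 TPM, a log2 fold change of 1.54 ± 0.13 (adjusted p = 0.00585). Serpinb9b, a member of the serpin family of protease inhibitors, rose from 0.945 ± 0.169 to 4.72 ± 0.354 TPM (1.56 ± 0.11, adjusted p = 0.00406). Trp73, which encodes the p53 family member p73, rose from 1.63 ± 0.317 to 4.97 ± 1.01 TPM (1.17 ± 0.15, adjusted p = 0.0261). Filip1 (1.48), Tg, the thyroglobulin gene (1.34), Igkc, the immunoglobulin kappa constant region (1.19), Tmtc3 (1.18) and Sdc4, which encodes the proteoglycan syndecan-4 (1.01), rose with adjusted p between 0.0200 and 0.0451. Tmtc3 lost its call after the GC and length correction, at 0.44 ± 0.27 with an adjusted p of 0.345. With single libraries left out, Serpinb9b lost its call without sgDhx37 4, and Trim2 without sgDhx37 1, 3 or 4. The other 6 genes lost theirs without vector 1 and without any one of the sgDhx37 libraries, and all of these but Filip1 also without vector 3.

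The 12 largest falls in sgDhx37 cells included Prss34, Lyz2, S100a8, Mcpt8, Ccl6, Prg2 and Clec4n. Of these, Prss34, S100a8, Mcpt8, Prg2 and Clec4n were under 1 TPM in every sgDhx37 library. They passed the filter through the vector libraries alone and could be tested only as falls. Prss34 and Mcpt8, which encode mast cell and basophil proteases, fell from 3.74 ± 1.65 to 0.237 ± 0.0973 TPM and from 3.52 ± 1.27 to 0.398 ± 0.0812 TPM. Lyz2, the lysozyme gene of macrophages and neutrophils, fell from 6.89 ± 1.998 to 1.10 ± 0.195 TPM. Prg2, which encodes the eosinophil major basic protein, fell from 2.19 ± 0.734 to 0.281 ± 0.215 TPM. The chemokine gene Ccl6 fell from 4.62 ± 1.24 to 1.06 ± 0.357 TPM, and Clec4n, which encodes the lectin Dectin-2, from 1.64 ± 0.342 to 0.418 ± 0.0732 TPM. S100a8, a calgranulin gene of neutrophils, had 3.50, 1.83, 3.98 and 1.30 TPM in vector 1 to 4 and was listed at 0 in all 4 sgDhx37 libraries, with an adjusted p of 0.0280. The log2 fold changes were -1.88 ± 0.22 (SE, adjusted p = 0.0207) for Prss34, -1.88 ± 0.18 (0.00883) for Lyz2 and -1.65 ± 0.20 (0.0247) for Mcpt8. They were -1.44 ± 0.19 (0.0280) for Ccl6, -1.30 ± 0.19 (0.0384) for Prg2 and -0.89 ± 0.12 (0.0280) for Clec4n. Without vector 1 and 2 all 7 genes stayed lower, with adjusted p between 0.00194 and 0.0216, and Prss34 was at -1.54 and Lyz2 at -1.60. None of the 7 kept its call without vector 1 or without any one of the sgDhx37 libraries, and without vector 3 Prss34 and Lyz2 alone did. Ms4a2 and Cpa3, which are also genes of basophils and mast cells and were picked after their values were seen, did not pass, at 0.60 and -0.27 (adjusted p = 0.426 and 0.598). Without vector 1 and 2 Cpa3 fell by 0.87 (adjusted p = 0.0139), and Ms4a2 was at -0.25 (adjusted p = 0.201).

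The remaining genes among the 12 largest falls were Cd7, Chd3, Tcp11l2, Pou2af1 and Rasgef1a. Cd7, which encodes a surface glycoprotein of T and NK cells, fell from 13.5 ± 3.87 to 4.81 ± 0.527 TPM (log2 fold change -1.28 ± 0.19, adjusted p = 0.0392). Chd3, which encodes an ATPase of the NuRD chromatin remodelling complex, fell from 127 ± 11.4 to 63.7 ± 4.58 TPM (-0.99 ± 0.11, adjusted p = 0.0160). Tcp11l2 fell from 22.03 ± 2.17 to 11.1 ± 0.443 TPM (-0.92 ± 0.10, adjusted p = 0.0183). Pou2af1, which encodes a coactivator of octamer transcription factors, and Rasgef1a, which encodes a Ras exchange factor, fell by 0.78 (adjusted p = 0.0357) and 0.78 (adjusted p = 0.0186). All of these 5 genes kept their call without vector 1 and 2 and after the GC and length correction, and lost it without vector 1 alone, without any one of the sgDhx37 libraries and with the replicate number as a block. Cd7, Pou2af1 and Rasgef1a also lost it without vector 3.

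**Figure D2:**
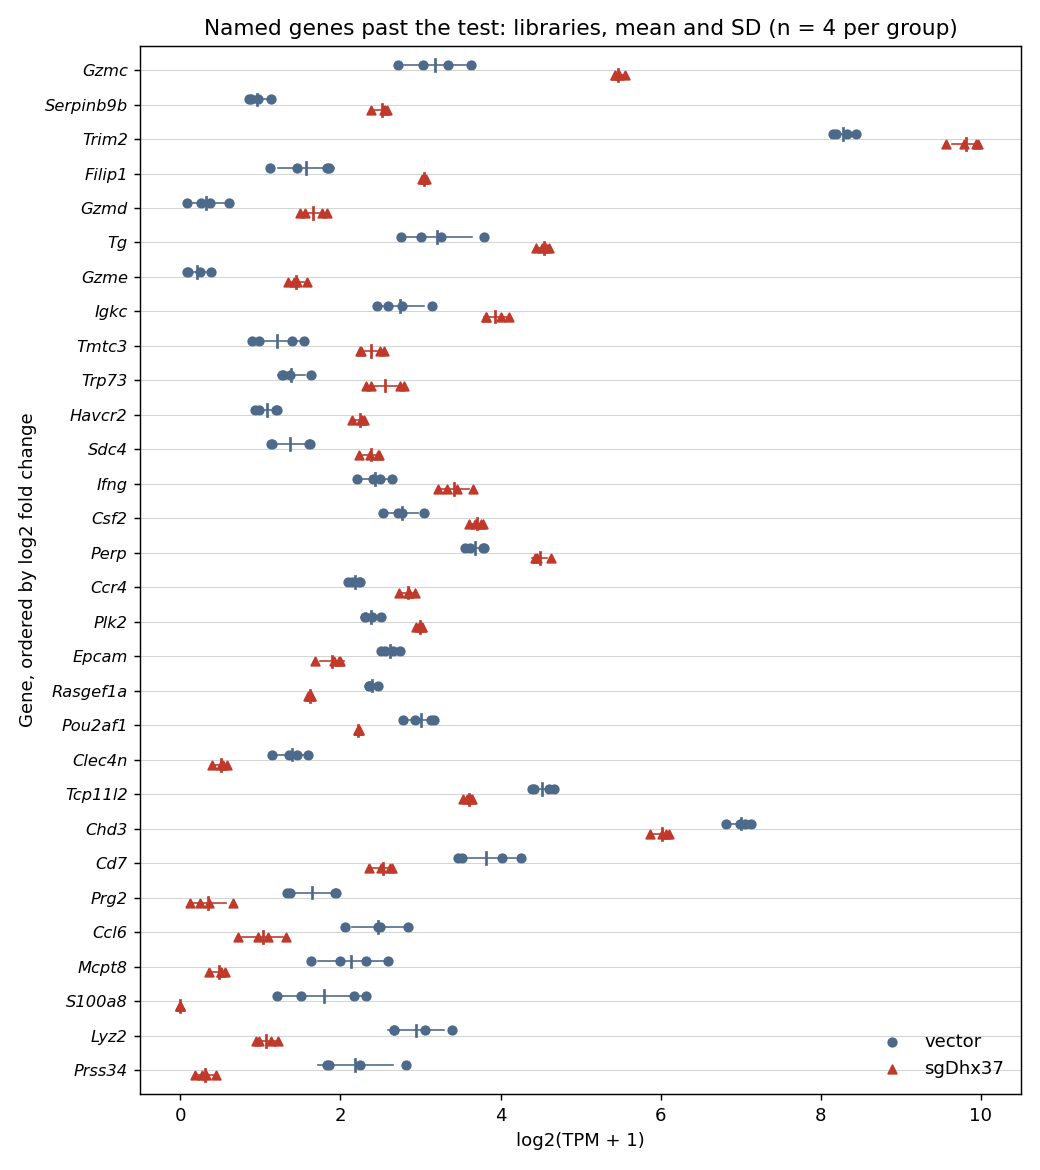
Values of log2(TPM + 1) in each library for the named genes past the test, ordered by log2 fold change; circles are vector and triangles sgDhx37 libraries, vertical ticks the group means and horizontal lines the SD (n = 4 per group). The libraries of the groups do not overlap for any gene shown, from Gzmc (8.33 to 43.4 TPM) at the top to Prss34 (3.74 to 0.237 TPM) at the bottom.

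In all, 50 of 11913 genes passed an adjusted p of 0.05, 32 higher and 18 lower in sgDhx37, and 1672 genes had an unadjusted p under 0.05. For each of the 50 genes the values of the groups did not overlap, which held for 14.2% of all tested genes, where chance gives 2.86%. Without vector 1 and 2, 1215 genes passed (893 higher, 322 lower), among them all 50 with the same direction. With vector 3 and 4 left out instead, 8401 passed (3843 higher, 4558 lower). After the GC and length correction of all 8 libraries 428 genes passed (213 higher, 215 lower), and 42 of the 50 were shared with the same direction. Rescaling by median-of-ratios size factors changed the split to 55 higher and 46 lower, and quantile normalization to 10 higher and 13 lower. Leaving out single libraries moved the count to 7 without vector 1, 12 without vector 3, 21 without vector 4, and left 54 without vector 2. It left 1 without sgDhx37 1, 4 without sgDhx37 2, 1 without sgDhx37 3 and 0 without sgDhx37 4. Without vector 1 and in each of these last 4 comparisons 0 genes passed as lower.

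Of the 37 gene lists fixed before the data were examined, 14 passed the camera test at an adjusted p of 0.05, 6 higher and 8 lower. None did with an estimated correlation between genes (lowest adjusted p = 0.160 with an estimated correlation). Without vector 1 and 2 the test called 22 lists, 13 higher and 9 lower, and 11 lists were called the same way in both. None held there with an estimated correlation either (lowest adjusted p = 0.251 with an estimated correlation). 9 lists were also called the same way after the GC and length correction: p53 targets, cytotoxic granule, S phase and G2 and M phase higher, and naive and memory, TCR signalling, migration and adhesion, histones and myeloid markers lower. With an estimated correlation after that correction, the p53 targets and the naive and memory list held (adjusted p = 0.0179 and 0.0426 with an estimated correlation). The other 7 did not, at 0.529 for cytotoxic granule, 0.529 for S phase, 0.0621 for G2 and M phase, 0.387 for TCR signalling, 0.422 for migration and adhesion, 0.732 for histones and 0.0859 for myeloid markers. Without vector 3 and 4, also chosen after the data were seen, 7 lists were called, 2 higher and 5 lower. Of the 9 lists above, TCR signalling and histones were among them. Not called there were the p53 targets (adjusted p = 0.185), cytotoxic granule (0.320), naive and memory (0.303), migration and adhesion (0.320), myeloid markers (0.346), G2 and M phase (0.0582) and S phase (0.617, with a median of -0.051). The fry test, which asks whether a list differs from no change and not from the other genes, called 10 lists, 7 of the 14 and further inhibitory receptors (adjusted p = 0.0237) and activation and co-stimulation (0.0212) as higher and NK cell markers (0.0136) as lower. Of the 35 splits of the 8 libraries into 4 and 4, 8 called as many lists as the real one. List medians below are relative to a median of all tested genes of -0.0080, or of 0.04 without vector 1 and 2.

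Genes of the p53 response and of cytotoxic granules were higher as groups. Of 27 tested p53 targets, 2 rose and none fell, and 8 rose and 2 fell when adjusted over the list alone. Perp, a p53 target that encodes a desmosome protein, rose from 11.9 ± 1.07 to 21.5 ± 1.49 TPM (0.80 ± 0.10, adjusted p = 0.0261). Plk2, which encodes a polo-like kinase, rose from 4.20 ± 0.351 to 6.96 ± 0.219 TPM (0.62 ± 0.09, adjusted p = 0.0442). Both lost their calls without vector 1, 3 or 4 and without any one of the sgDhx37 libraries. The list's median log2 fold change was 0.40 (camera adjusted p = 7.4e-04; adjusted p = 0.160 with an estimated correlation). Its mean log2(TPM + 1) was 4.12 to 4.21 in the vector and 4.52 to 4.61 in the sgDhx37 libraries. Cdkn1a, which encodes the cell cycle inhibitor p21, had 24.1 ± 8.12 TPM in vector and 44.6 ± 2.49 TPM in sgDhx37 (adjusted p = 0.167). It passed without vector 1 and 2, at 1.31 ± 0.08 (adjusted p = 7.2e-04), where 16 p53 targets rose and 1 fell and the list's median was 0.29. Of 17 tested cytotoxic granule genes, Gzmc, Gzmd and Gzme rose and none fell, and 9 rose when adjusted over the list alone (median 0.44, camera adjusted p = 7.1e-04; adjusted p = 0.292 with an estimated correlation). Gzmb, the granzyme B gene, had 749.5 ± 123 TPM in vector and 1235 ± 58.0 TPM in sgDhx37, with an adjusted p of 0.0726, and passed without vector 1 and 2 at 0.91 ± 0.06 (adjusted p = 0.00132). The median of the cytotoxic list was 0.37 without vector 1 and 2 and 0.07 after the GC and length correction, with adjusted p of 5.9e-05 and 0.0161 (adjusted p = 0.315 and 0.529 with an estimated correlation). Cdkn1a and Gzmb were singled out after their values were seen.

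The other effector lists did not pass camera as groups. Among 15 tested effector cytokines and chemokines, Csf2 and Ifng rose and none fell, 4 rose when adjusted over the list alone, and the list had a median of -0.0049, a mean of 0.09 and an upward test (adjusted p = 0.585). Among 19 inhibitory receptors, Havcr2 rose and none fell, and 2 rose and 1 fell when adjusted over the list alone (median 0.05, adjusted p = 0.510). Of 30 activation and co-stimulation genes 1 rose, and 5 rose when adjusted over the list alone (median 0.07, adjusted p = 0.0883). This list passed without vector 1 (adjusted p = 0.0386) or vector 2 (adjusted p = 0.0151), with either change of the filter (adjusted p = 0.0493 and 0.0233), and without vector 1 and 2 with a median of 0.16 (adjusted p = 0.0211; adjusted p = 0.466 with an estimated correlation). None of 28 effector and exhaustion transcription factors passed, while 4 rose and 3 fell when adjusted over the list alone (median 0.06, adjusted p = 0.639). None of 33 NF-kB targets passed over all genes or when adjusted over the list alone (median -0.11, adjusted p = 0.544).

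Genes of naive and memory T cells, of T cell receptor signalling and of migration were lower as groups. None of 26 tested naive and memory genes passed over all genes, and 1 rose and 5 fell when adjusted over the list alone (median -0.30, camera adjusted p = 9.0e-04; adjusted p = 0.160 with an estimated correlation). Its members with the smallest p were Sidt1, at 37.3 ± 2.03 TPM in vector and 26.1 ± 0.527 TPM in sgDhx37 (adjusted p = 0.0623), and S1pr1. The latter, which encodes the receptor that guides lymphocytes out of lymph nodes, stood at 64.5 ± 2.01 and 45.6 ± 3.71 TPM (adjusted p = 0.0826). None of 31 TCR signalling genes passed over all genes or when adjusted over the list alone (median -0.31, camera adjusted p = 9.6e-05; adjusted p = 0.491 with an estimated correlation). Prkcq, which encodes protein kinase C theta, had 171 ± 4.93 and 136 ± 5.42 TPM, and Plcg1, the phospholipase C gamma 1 gene, 79.6 ± 11.5 and 61.6 ± 2.86 TPM. The medians of these lists were -0.17 and -0.08 without vector 1 and 2, with adjusted p of 2.1e-08 and 2.7e-04 (adjusted p = 0.251 and 0.351 with an estimated correlation). Of 22 migration and adhesion genes, 5 fell and 1 rose when adjusted over the list alone. Over all genes only the chemokine receptor gene Ccr4 passed, and it rose from 3.53 ± 0.216 to 6.17 ± 0.395 TPM (0.66 ± 0.10, adjusted p = 0.0351), a call lost when any single library other than vector 2 was left out. This list had a median of -0.29 (camera adjusted p = 0.0354; adjusted p = 0.424 with an estimated correlation), and lost its call without vector 3 (adjusted p = 0.0995) or vector 4 (adjusted p = 0.0845), with quantile normalization (adjusted p = 0.0709) and with no filter on low values (adjusted p = 0.137). Its median was -0.12 without vector 2 (adjusted p = 0.00492) and -0.13 without vector 1 and 2 (adjusted p = 0.00135; adjusted p = 0.251 with an estimated correlation).

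NK-type receptors and terminal effector genes were higher as a list, with a median of 0.66 over 11 tested genes (camera adjusted p = 0.0198; adjusted p = 0.646 with an estimated correlation). None passed over all genes, and 4 rose and 2 fell when adjusted over the list alone. Gzma, the granzyme A gene, had 7.90 ± 0.451 TPM in vector and 11.1 ± 0.550 TPM in sgDhx37, and Fcer1g, which encodes an activating receptor adaptor, 1.85 ± 0.265 and 0.995 ± 0.333 TPM. The list lost its call without vector 1 and 2 (median 0.16, adjusted p = 0.461) and after the GC and length correction (median 0.07, adjusted p = 0.538), and with array weights (median 0.14, adjusted p = 0.182).

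Genes of DNA replication and mitosis were higher as groups. Histone genes were lower as a list, but not than in every vector library. The mean log2(TPM + 1) of the histone list was 2.37, 2.36, 5.42 and 1.56 in vector 1 to 4. In the sgDhx37 libraries it was 1.51 to 2.04, so vector 4 lay within their range. None of 52 tested S phase genes and none of 54 G2 and M phase genes passed over all genes or when adjusted over the list alone. Their medians were 0.12 (camera adjusted p = 0.00217; adjusted p = 0.422 with an estimated correlation) and 0.15 (camera adjusted p = 0.0107; adjusted p = 0.199 with an estimated correlation). In the comparison without vector 1 and 2, 25 S phase genes rose and none fell, with a median of 0.24, and 11 G2 and M phase genes rose and none fell, with a median of 0.14. Tipin and Gins1, which encode replication fork proteins, had 106 ± 21.1 and 27.0 ± 0.460 TPM in vector and 157 ± 11.1 and 33.5 ± 1.12 TPM in sgDhx37. The mitotic genes Psrc1 and Dlgap5 had 49.7 ± 10.8 and 79.0 ± 20.6 TPM in vector and 68.7 ± 3.41 and 108 ± 2.26 TPM in sgDhx37. The S phase call was lost without vector 3 (adjusted p = 0.0567), vector 4 (adjusted p = 0.0519) or both (adjusted p = 0.617), and the G2 and M phase call without both (adjusted p = 0.0582). None of 19 replication-dependent histone genes passed over all genes or when adjusted over the list alone, with a median of -1.24 (camera adjusted p = 2.6e-04; adjusted p = 0.646 with an estimated correlation). Much of that median came with vector 3, where Hist1h4d stood at 164 TPM and Hist1h2ab at 56.2 TPM against 3.38 to 10.8 and 2.13 to 8.38 TPM in the other 7 libraries; without vector 3 the median was -0.44 (adjusted p = 0.0306), and without vector 4 it was -1.87.

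Genes that assemble ribosomes, the process in which DHX37 acts, did not pass as groups. None of 46 tested genes of the small subunit processome and 40S maturation, none of 47 60S assembly genes and none of 31 RNA polymerase I and III genes passed over all genes or when adjusted over the list alone. The small subunit list had a median of 0.08 (adjusted p = 0.370) and, without vector 1 and 2, of 0.09 (adjusted p = 0.0612), where Nop56, which encodes a box C/D snoRNP protein, Utp4 and Pno1 rose by 0.30, 0.28 and 0.28. The 60S list had a median of -6.8e-04, a mean of 0.13 and an upward test (adjusted p = 0.555), and the polymerase list a median of -0.15, a mean of 0.0049 and a downward test (adjusted p = 0.3003). Cytosolic ribosomal protein genes were lower as a list, with a median of -0.35 over 76 genes, none of which passed over all genes or when adjusted over the list alone (camera adjusted p = 2.1e-08; adjusted p = 0.646 with an estimated correlation). Rps6 had 2805 ± 546 TPM in vector and 2174 ± 76.3 TPM in sgDhx37. The median of this list was -0.15 without vector 2 (adjusted p = 8.4e-07) and 0.0020 without vector 1 and 2 (adjusted p = 0.286). After the GC and length correction it was -0.27 (camera adjusted p = 5.6e-08; adjusted p = 0.529 with an estimated correlation). With that correction and without vector 1 and 2 it was -0.068 (camera adjusted p = 2.3e-04). The 13 mitochondrially encoded genes had a median of 1.22 (camera adjusted p = 6.5e-04; adjusted p = 0.646 with an estimated correlation), and none passed over all genes or when adjusted over the list alone. For this list mt-Nd1 had 2283 ± 1811 TPM in vector and 4249.6 ± 865 TPM in sgDhx37, and mt-Co2 had 5936 ± 4348 and 10455 ± 1719.7 TPM. Their list had a median of 0.08 and a downward test without vector 1 and 2 (adjusted p = 0.865), and lost its call with array weights (adjusted p = 0.459). It kept its call after the GC and length correction (median 0.71, camera adjusted p = 7.9e-04; adjusted p = 0.529 with an estimated correlation). With that correction and without vector 1 and 2 the call was lost (median 0.096, camera adjusted p = 0.205).

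Metabolic, growth and stress genes did not pass as groups in the comparison of all 8 libraries without weights or correction. Their direction depended on which vector libraries were left out. Of 34 tested glycolysis genes none passed with all 8 libraries, 2 rose when adjusted over the list alone, and the median was 0.06 (adjusted p = 0.307). Without vector 1 and 2, 19 rose and none fell, among them Hk2, which encodes hexokinase 2, by 0.57 and Ldha, the lactate dehydrogenase A gene, by 0.56. The median was then 0.34 (adjusted p = 2.5e-09; adjusted p = 0.251 with an estimated correlation), and without vector 3 and 4 it was -0.22 (adjusted p = 0.320). This list also passed without vector 2 alone (adjusted p = 5.5e-04) and after the GC and length correction (adjusted p = 7.9e-04; adjusted p = 0.529 with an estimated correlation). Of 37 ATF4 and integrated stress response genes none passed, 2 rose when adjusted over the list alone, and the median was 0.05 (adjusted p = 0.156). With vector 1 and 2 left out, 20 rose, 1 fell and the median was 0.26 (adjusted p = 2.0e-06; adjusted p = 0.251 with an estimated correlation), and with vector 3 and 4 left out it was -0.20 (adjusted p = 0.598). These genes also passed without vector 1 (adjusted p = 0.0386), without vector 2 (adjusted p = 9.8e-04) and after the GC and length correction (adjusted p = 7.4e-05; adjusted p = 0.271 with an estimated correlation). The 40 MYC and growth genes had a median of -0.10, a mean of 0.0029 and a downward test (adjusted p = 0.847), with none past the test over all genes or when adjusted over the list alone. When vector 1 and 2 were left out, 15 of them rose, none fell and the median was 0.24 (adjusted p = 5.3e-09; adjusted p = 0.315 with an estimated correlation), whereas without vector 3 and 4 the list was lower, with a median of -0.41 (adjusted p = 0.0414). The 76 nuclear-encoded respiratory chain genes had a median of -0.19 (adjusted p = 0.0547), with none past the test over all genes or when adjusted over the list alone. With vector 1 and 2 left out, 15 rose, none fell and the median was 0.18 (adjusted p = 5.3e-09; adjusted p = 0.351 with an estimated correlation). The respiratory list was lower without vector 3 and 4 (median -0.54, adjusted p = 3.5e-05), without vector 3 (-0.33, adjusted p = 0.00288), without vector 4 (-0.28, adjusted p = 0.0108) and without sgDhx37 3 (-0.20, adjusted p = 0.0314). It was also lower with no filter (adjusted p = 0.0197) and with the replicate number as a block (adjusted p = 0.0256). With array weights the MYC and respiratory lists were higher (medians 0.19 and 0.13, adjusted p = 5.0e-06 and 6.1e-04).

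Among the remaining pathway lists, none passed in the comparison of all 8 libraries without weights or correction. The 31 IL-2 and STAT5 targets had a median of -0.05, a mean of 0.03 and an upward test (adjusted p = 0.605; 4 rose when adjusted over the list alone). The 23 unfolded protein response genes had a median of -0.0070, a mean of 0.09 and an upward test (adjusted p = 0.670). None of them passed over all genes or when adjusted over the list alone. The 27 cholesterol synthesis genes had a median of -0.08, a mean of 0.02 and an upward test (adjusted p = 0.971; 1 rose when adjusted over the list alone). These lists passed without vector 1 and 2, with medians of 0.17, 0.13 and 0.16 (adjusted p = 2.7e-04, 0.00494 and 8.9e-04), and with an estimated correlation their adjusted p values were 0.351, 0.351 and 0.346. There Lif, which encodes leukemia inhibitory factor, rose by 1.08 and Scd1, the stearoyl-CoA desaturase gene, by 0.81. The 45 interferon-stimulated genes had a median of -0.0042, a mean of 0.07 and a downward test (adjusted p = 0.555; 1 fell when adjusted over the list alone). They passed without vector 1 and 2 with a median of -0.06 (adjusted p = 0.00322; adjusted p = 0.418 with an estimated correlation). The 28 apoptosis regulators had a median of -0.10, a mean of 0.02 and a downward test (adjusted p = 0.555). The 25 immediate early and heat shock genes had a median of -0.14, a mean of 0.03 and a downward test (adjusted p = 0.600). Neither of the latter lists had a member past the test, over all genes or when adjusted over the list alone.

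The lists of myeloid, of erythroid and platelet, and of stromal markers were lower in sgDhx37, the last 2 with few tested members. Of 8 tested myeloid markers, Lyz2 and S100a8 fell and none rose, 3 fell when adjusted over the list alone, and the median was -0.27 (camera adjusted p = 0.00232; adjusted p = 0.160 with an estimated correlation). In the comparison without vector 1 and 2, 4 fell and the median was -0.29 (adjusted p = 2.7e-04; adjusted p = 0.251 with an estimated correlation); without vector 3 and 4 the list lost its call (adjusted p = 0.346). Of 6 erythroid and platelet markers none passed over all genes and 3 fell when adjusted over the list alone (median -0.42, camera adjusted p = 0.0107; adjusted p = 0.199 with an estimated correlation). Here the platelet genes Gp1ba and Pf4 had 1.83 ± 0.213 and 2.63 ± 0.354 TPM in vector and 1.09 ± 0.192 and 1.32 ± 0.631 TPM in sgDhx37. Of 3 stromal and epithelial markers Epcam, an epithelial adhesion gene, fell from 5.14 ± 0.438 to 2.73 ± 0.360 TPM (-0.72 ± 0.11, adjusted p = 0.0467), a call lost when any single library was left out. In this list 2 fell when adjusted over the list alone (median -0.35, camera adjusted p = 0.0161; adjusted p = 0.315 with an estimated correlation). Its other members Pecam1 and Tagln were at -0.19 and -0.0048 without vector 1 and 2 (limma adjusted p = 0.0557 and 0.982). The erythroid and stromal lists lost their calls after the GC and length correction (adjusted p = 0.105 and 0.0926), as did Epcam (0.0532), and without vector 3 (0.0590 and 0.0567), vector 4 (0.0872 and 0.0570) or both (0.571 and 0.320); the stromal list also lost it with no filter (0.109). The 11 B cell markers, of which only Igkc rose, had a median of -0.02, a mean of 0.08 and an upward test (adjusted p = 0.699; 1 rose when adjusted over the list alone). The 5 NK cell markers had a median of -0.52 (adjusted p = 0.157; 1 rose and 3 fell when adjusted over the list alone). The 7 CD4 and regulatory T markers had a median of -0.05, a mean of 0.05 and an upward test (adjusted p = 0.869; 1 rose and 1 fell when adjusted over the list alone). The 9 MHC class II and antigen presenting cell genes had a median of 0.15 (adjusted p = 0.423; 1 rose when adjusted over the list alone). They passed without vector 1 and 2 with a median of 0.36 (adjusted p = 0.00494; adjusted p = 0.346 with an estimated correlation), and after the GC and length correction (adjusted p = 0.0297; adjusted p = 0.387 with an estimated correlation). The 4 gamma delta T markers had a median of -0.20 (adjusted p = 0.228, with none past the test when adjusted over the list alone). These passed without vector 1 and 2 with a median of -0.44 (adjusted p = 0.0117; adjusted p = 0.346 with an estimated correlation), without vector 2 alone (adjusted p = 0.0373) and after the GC and length correction (adjusted p = 0.0339; adjusted p = 0.286 with an estimated correlation).

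**Figure D3:**
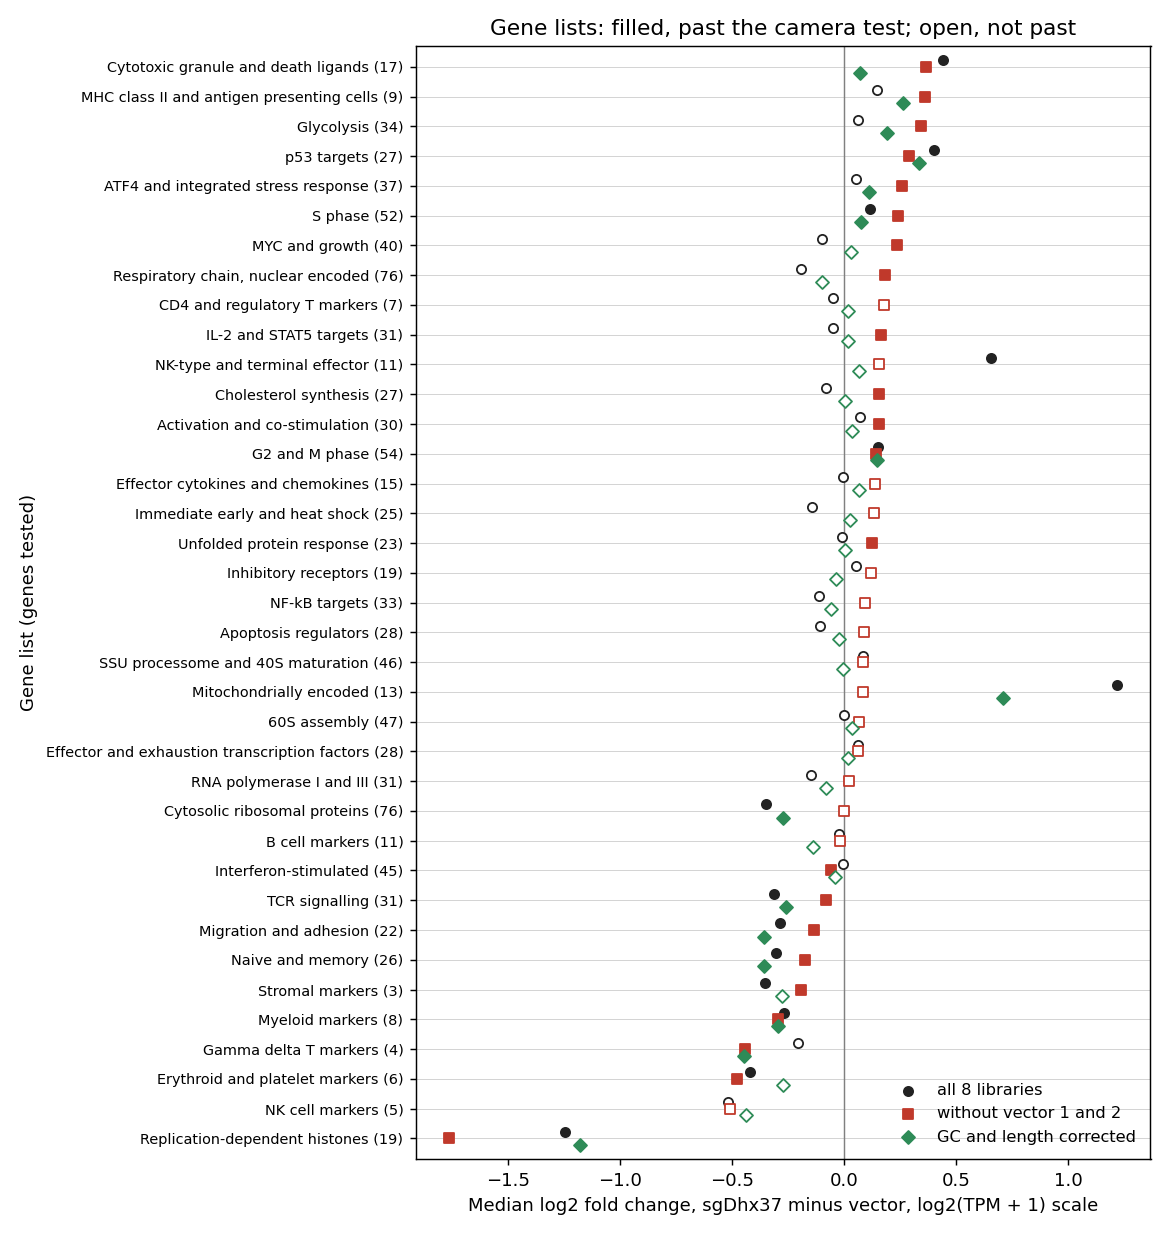
Median log2 fold change (sgDhx37 minus vector, log2(TPM + 1) scale) of the 37 gene lists, with the number of genes tested in brackets; circles use all 8 libraries, squares leave out vector 1 and 2, and diamonds follow the GC and length correction, filled where the camera adjusted p is under 0.05. The mitochondrially encoded list moves from 1.22 to 0.08 without vector 1 and 2, while the p53 targets stay between 0.29 and 0.40 in the 3 comparisons.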

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

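The tests of the difference between the vector libraries were chosen after the result was seen, while the search for single libraries far from the rest of their group was planned. That search compared the gap of the most extreme library with the range of its group of 4, over 174 groups of values, and found 15 such libraries; chance alone gives about 1 in 20 groups, here 8.7.

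Among genes past the test, Serpinb9b was low in sgDhx37 2, at 4.20 TPM against 4.84 to 4.96 in the other sgDhx37 libraries, Perp was high in sgDhx37 1, at 23.7 TPM against 20.6 to 20.9, and Rasgef1a was high in vector 2, at 4.55 TPM against 4.14 to 4.18. In sgDhx37, Plcg1 stood at 65.9 TPM in library 2 against 59.7 to 60.6, Psrc1 at 73.9 TPM in library 3 against 66.9 to 67.2, and mt-Nd1 at 5534 TPM in library 1 against 3715 to 3999. The histone genes Hist1h4d and Hist1h2ab stood at 164 and 56.2 TPM in vector 3 against 4.59 to 10.8 and 3.36 to 8.38 TPM in the other vector libraries.

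For lists the value was the mean log2(TPM + 1) of the tested members. RNA polymerase I and III genes were high in vector 2, at 4.80 against 4.65 to 4.66, and low in sgDhx37 2, at 4.66 against 4.70 to 4.71. The p53 targets were low in vector 1, at 4.12 against 4.21 in each other vector library, and S phase genes high in vector 2, at 5.94 against 5.80 to 5.82. Cholesterol synthesis genes were low in sgDhx37 2, at 5.16 against 5.22 to 5.24. Migration and adhesion genes were high in vector 2, at 6.02 against 5.83 to 5.86, and low in sgDhx37 2, at 5.69 against 5.74 to 5.75.

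Vector libraries 1 and 2 differed from vector 3 and 4 across most of the transcriptome, and vector 2 supplied 4 and sgDhx37 2 supplied 5 of the 15 values above. A lower mitochondrial share alone would move all other genes by 1 factor, a log2 difference of 0.12, yet among genes outside the mitochondrial genome the medians of the 20% with the highest and the 20% with the lowest GC content lay 1.69 apart, which argues against it. GC content and transcript length together explained 48.6% of the variance of the difference across genes, so a bias in library preparation or amplification remains a candidate explanation for part of it. A difference in the cells could also give such a trend, and no biological explanation was tested, since the labels name no difference among the 4 vector cultures.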

How the results depend on the processing

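The comparisons without vector 1 and 2, without vector 3 and 4 and with the GC and length correction were chosen after the data were seen; the other alternatives were planned. All 30 named genes past the test kept their direction under every alternative in which they were tested. A filter at a mean of 5 TPM left 12 of them. Because the groups did not overlap for these genes, most alternatives, such as leaving out a library, could not turn their direction. Over all alternatives they kept their call in 450 cases and lost it in 282. The number of genes past the test was 50 and became 4 with that filter, 101 with median-of-ratios scaling, 23 with quantile normalization, 225 with array weights, 1215 without vector 1 and 2, 8401 without vector 3 and 4, 428 with the GC and length correction, 2017 with that correction without vector 1 and 2, 120 at an adjusted p of 0.1, 21 with a log2 fold change of at least 1, and between 0 and 54 with single libraries left out. It stayed within 1.5 times of 50 under the other alternatives without a block. The number of lists past the test was 14 and became 24 with array weights, 22 without vector 1 and 2, 7 without vector 3 and 4, 23 with the GC correction without vector 1 and 2 and 0 with an estimated correlation, was 10 with fry, and lay between 11 and 18 with single libraries left out. The cause of these changes was not tested beyond the smaller numbers of genes or libraries. Depth is unknown and limits the genes near 1 TPM by an amount the table does not show.

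The Dhx37 difference of -0.30 shrank to -0.089 ± 0.077 with the GC and length correction, turned to 0.022 with array weights, 0.083 without vector 1 and 2 and 0.028 with the GC correction without vector 1 and 2, and passed the threshold at -0.68 without vector 3 and 4; with single libraries left out it lay between -0.45 and -0.12. The difference in mean score on the first principal component was 41.0 in the main comparison. It was -29.8 without vector 1 and 2 and -29.1 with the GC correction without them. Components were computed anew each time and their sign is arbitrary, so these values do not show a change of direction. Among lists, the median of MYC and growth genes, or its test, turned direction with quantile normalization (-0.069), array weights (0.19), without vector 1 and 2 (0.24), with the GC correction (0.032) and with that correction without vector 1 and 2 (0.17), and lay between -0.24 and 0.074 with single libraries left out. Respiratory chain genes turned with array weights (0.13), without vector 1 and 2 (0.18) and with the GC correction without them (0.12), and lay between -0.33 and 0.038 with single libraries left out. Cholesterol synthesis turned in test but not in median with no filter (-0.072) and turned with the GC correction (0.0031), and lay between -0.14 and 0.045 with single libraries left out; IL-2 and STAT5 targets lay between -0.16 and 0.098. Mitochondrially encoded genes turned in test but not in median without vector 1 and 2 (0.084). Without vector 3 and 4, glycolysis (-0.22), ATF4 targets (-0.20) and MHC class II genes (-0.29) turned in median and test, and interferon-stimulated genes (-0.046), IL-2 and STAT5 targets (-0.38), the unfolded protein response (-0.29) and cholesterol synthesis (-0.22) in test but not in median.

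With the replicate number as a replicate block, 0 genes passed in limma, and 2 did with the block and the GC and length correction; MYC and growth genes were at 0.032 and cholesterol synthesis at 0.0031 in the latter, and cholesterol synthesis at -0.079 with the block alone. The numbers are not said to pair cultures. The deviations of libraries with the same number correlated at -0.420, -0.0172, -0.330 and -0.159, and no library correlated best with its own number. In vector these deviations are dominated by the difference of libraries 1 and 2 from 3 and 4, so they cannot exclude a pairing. With the block 15 lists passed.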

Other observations

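All tests of explanations in this part were chosen after the results were seen.

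Several genes past the test lie outside the naming rule and are named here after their values were seen. Il12rb2, which encodes a chain of the interleukin 12 receptor, rose from 105 ± 14.1 to 180 ± 10.3 TPM, Il18 from 6.25 ± 0.604 to 11.7 ± 0.723 TPM, and Tnfsf4, which encodes OX40 ligand and is the 1 activation and co-stimulation gene past the test, from 19.6 ± 1.30 to 35.3 ± 2.75 TPM (mean ± SD, n = 4 each; limma adjusted p = 0.0442, 0.0261 and 0.0258). Bst1, which encodes an ADP-ribosyl cyclase of the cell surface, rose from 5.24 ± 0.758 to 10.4 ± 0.657 TPM. Ripor2, which encodes an inhibitor of RhoA, fell from 118 ± 8.98 to 69.2 ± 3.60 TPM, and Thbs1, the thrombospondin 1 gene, from 1.33 ± 0.0461 to 0.391 ± 0.0980 TPM. The adjusted p of Tnfsf4 and Bst1 was 0.112 and 0.0842 after the GC and length correction.

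Some transcription factor genes of activated T cells did not pass with all 8 libraries and did without vector 1 and 2, a comparison chosen after the data were seen. Batf3 was at 17.2 ± 2.28 TPM in sgDhx37, against 8.91, 9.08, 5.81 and 4.74 TPM in vector 1 to 4, and rose by 1.53 ± 0.13 (SE, log2) in that comparison (limma adjusted p = 0.00286). Irf4 and Bhlhe40 rose by 0.67 and 0.66 there, and Tox, a factor of exhausted T cells, fell by 0.52, from 8.52 and 8.11 TPM in vector 3 and 4 to 5.48 ± 0.268 TPM in sgDhx37. With all 8 libraries the adjusted p of these 4 genes was 0.0623, 0.181, 0.345 and 0.111. In vector 3, which held the high histone values, Lars2 stood at 22565 TPM and Gm20594 at 22115 TPM, against 271 to 5057 and 1950 to 3170 TPM in the other 7 libraries.

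The number of differential genes was larger than in any other split: of the 35 splits of the 8 libraries into 4 and 4, 1, the real one, gave as many as 50 genes, and the highest other split gave 1. A share of 1 in 35 is the smallest this comparison can give. Many other splits put vector 1 and 2 into different groups, which widens the spread within both groups and leaves few genes to call. Splits that kept vector 1 and 2 together also gave 0 or 1 gene, but mixed sgDhx37 with vector libraries. For the lists chance cannot be excluded, since 8 of the 35 splits gave as many as the real 14 and the highest other split gave 20. Each of the other splits with as many lists put vector 1 and vector 2 into different groups and kept vector 3 and 4 together. Each differs from the real split by the exchange of 1 vector library for 1 sgDhx37 library. Such splits keep much of the real grouping, so their counts do not measure chance alone. What raised these counts was not tested.

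Higher transcripts of granzyme, cytokine and p53 target genes past the test are a pattern found and tested on the same data. After the GC and length correction of all 8 libraries, 6 of the 7 genes called stayed higher. Of all 50 genes past the test 42 kept their call there, so this is not particular to the pattern. Genes past the test did not overlap vector 3 and 4 either, so the outcome was close to fixed beforehand. The count therefore does not weigh GC bias of vector 1 and 2 as a cause. Ifng went from 0.98 ± 0.14 to 0.73 ± 0.18 (SE) and lost its call, as its change shrank and its spread grew. Sharing of reads among granzyme paralogs would leave their sum equal. The summed TPM of Gzmc, Gzmd, Gzme, Gzmf and Gzmg was 9.11 ± 2.93 in vector and 49.0 ± 1.503 in sgDhx37. This was a log2 difference of 2.35 (exact two-sided permutation test, p = 0.0286, the smallest that 4 against 4 can give). Gzmc alone held 8.33 TPM in vector and 43.4 TPM in sgDhx37. The sum therefore does not show whether Gzmd and Gzme rose themselves or took up reads of Gzmc. Gzmb was not part of it. A p53 response may be part of it as a hypothesis. The median of 27 p53 targets with the GC correction without vector 1 and 2, 0.26, was at percentile 100 of 10000 random lists. These were matched on mean expression and leave out the correlation between targets. In camera with an estimated correlation the list had adjusted p = 0.160 with all 8 libraries and adjusted p = 0.251 without vector 1 and 2. After the GC and length correction of all 8 libraries it had adjusted p = 0.0179 with an estimated correlation. Without vector 3 and 4 the list had a camera adjusted p = 0.185. Whether loss of DHX37 or DNA cutting by any active guide lies behind this cannot be told apart, because the number of libraries with another active guide is 0 and the vector is described as empty.

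Lower transcripts of 7 basophil and myeloid genes, picked from the genes past the test, are a further pattern. After the GC and length correction without vector 1 and 2, 7 of the 7 genes called stayed lower. This outcome was close to fixed beforehand, since genes past the test did not overlap vector 3 and 4 either. All 50 genes past the test kept their call there. The count shows that these genes were also lower than in vector 3 and 4, and does not weigh GC bias as a cause. Fewer basophils or mast cells in the sgDhx37 cultures are a candidate explanation that stays open. In a list of 20 basophil and mast cell genes, written after the data were seen and with 5 members that are also on another of the gene lists, 8 of the 16 genes not called were lower in sgDhx37 than in both pairs of vector libraries, against 5.33 if the 3 means came in random order (one-sided exact binomial p = 0.127), and these were 8 of the 10 genes below the filter and 0 of the 6 tested. Its members Prss34 and Mcpt8 reached at most 6.08 and 5.03 TPM in any library, and Cpa3 and Ms4a2 were higher in vector 3 and 4 (5.81 to 7.51 TPM) than in vector 1 and 2 (1.26 to 2.22 TPM), with Cpa3 lower in sgDhx37 without the latter (-0.87, adjusted p = 0.0139), so these few genes of low abundance do not decide it.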
